A study of Mus musculus with 6 samples.

How the data were processed

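Total RNA of mouse liver was made into small RNA libraries with adapters ligated to both ends of the RNA, amplified by PCR, size-selected for short inserts and sequenced as single reads on an Illumina instrument, per the labels' protocols. No molecular identifiers are named there. Ligation favours some small RNAs over others, so a share of reads is not a share of molecules. The deposited table gives raw counts, as whole numbers, of the reads of 1 cleaned library for each entry of a mature miRNA list, per the file headers. The column name matches the title of Cre-miR122 replicate 2 and of no other sample, and 0 library columns had no matching sample. The counting program, its version, its settings and the release of the miRNA list are not given in the sources used here. The mm10 build is named by the submitters' processing notes. Total reads per library, before matching to miRNAs, are not given in the sources used here, so shares are of matched reads and the depth is the 8163802 reads over distinct sequences.

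The table has 48885 entries of 271 species codes. Entries with an identical sequence had equal counts in every case (0 exceptions), so summing over entries would count a read repeatedly, and each distinct sequence was used once. Counting was checked with 1129 pairs in which a shorter entry is the start of an entry up to 5 nt longer. The longer entry had more reads in 591 pairs, which cannot happen if a read counts for every entry that it contains. Reads were taken as counted where the whole read equals the entry. Rules that give each read to 1 longest or best matching sequence are not excluded by this check, and under them an entry could also hold reads with ends that no entry records. Mouse values are the reads of the 1963 distinct mouse sequences (1978 entries), as a percentage of their sum. Entries of identical sequence, such as miR-486a-5p and miR-486b-5p, are given under both names.

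Entries of other species were searched for exact matches in the 2202 annotated mouse miRNA hairpins of GENCODE release M21 (GRCm38, the same assembly as mm10). An entry was taken as an end variant of a mouse mature sequence if, at every place it was found, it overlapped that sequence the most and by at least 15 nt. Of the mouse sequences, 1896 lay in an annotated hairpin, with 6660630 of the 6661069 mouse reads. Values with end variants use the sum over mouse sequences and end variants, 8032208 reads, as the denominator. Coordinates are 1-based and come from the same annotation. Entries in no mouse hairpin were compared with hairpin sequences allowing up to 2 other bases at the 3′ end, or 1 substitution elsewhere.

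Shares have exact Clopper-Pearson 95% intervals and ratios of reads have exact intervals from the binomial distribution given the sum of both counts. With 1 library these cover counting error alone, and no interval describes differences between animals. Intervals and assignment were tested on simulated data. In 20 simulated libraries with the shares and total of the real one, in which 200 sequences were changed, 95.8% of the intervals of the 303 sequences with at least 10 reads held the true share. The interval lay wholly on the correct side of the unchanged share for 99.9% of sequences lowered to 0.25 of their share, 93.2% of those lowered to 0.5, 95.3% of those raised 2-fold and 100% of those raised 4-fold. These folds were applied first, and all shares were then rescaled to the same total. The simulated changes therefore differ from the folds named. The simulated reads were drawn independently, as the intervals assume, so these rates check the calculation only. They do not show coverage for a library with PCR copies. Of 190 sequences drawn from hairpins with shifted ends, 99.5% were assigned to the sequence they came from and 0% to another.

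The comparison of Cre-miR122 with Cre that the design implies, planned as tests on counts of 3 against 3 libraries over miRNAs, miR-122, miRNA lists, other features and RNA classes, could not be run with 1 library. The table holds miRNAs only, so 4 planned lists of other genes (miR-122 target mRNAs, hepatocyte mRNAs, cardiac mRNAs and mitochondrial RNAs) were not used here. The 14 miRNA lists were fixed before the data were examined. The miRNAs named are the miR-122 features, the 10 most abundant miRNAs and up to 4 of the highest members of each list, under a rule also fixed before the data were examined. Any other miRNA named is said to have been chosen after its values were seen. Alternatives recomputed were the total over all sequences, sequences with at least 10 reads, shares without miR-122 features, counting of end variants and shares without miR-148a-3p. The last 2 were chosen after seeing the data. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.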

Results

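Small RNA was sequenced from the livers of mice injected with an adeno-associated virus of serotype 9 (AAV9), a vector used to carry genes into mouse tissues. The vector carried Cre recombinase under the promoter of Tnnt2, the gene of cardiac troponin T, which is used to restrict expression to heart muscle cells. In the Cre-miR122 group the vector also carried an element named after miR-122, the main microRNA (miRNA) of hepatocytes. The labels do not say whether this element encodes the miRNA or holds binding sites for it. The stated question was how the vector with this element affects the miRNAs of the liver. The labels name 6 libraries, 3 of the Cre-miR122 group (replicates 1, 2 and 4) and 3 of the Cre group (replicates 10, 11 and 12). Counts of 1 library, Cre-miR122 replicate 2, were analysed here, and the other 5 libraries were not analysed here. The values below therefore describe 1 library, with no replicate and no control, and no difference between the groups was tested.

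The library held 8163802 reads over 30721 distinct mature miRNA sequences of all species in the table, of which 1458 had at least 1 read. Mouse mature sequences held 6661069 of these reads, which is 81.6% (exact Clopper-Pearson 95% interval 81.57 to 81.62). Of 1963 distinct mouse sequences, 546 had a count, 303 had at least 10 reads and 22 had at least 10000. A count of 0 allows a share of up to 4.5e-05% of the mouse reads, taking 3 reads as the floor. All intervals and this floor cover the counting error of reads only, because 1 library was analysed. PCR copies of a molecule were counted as separate reads, so the intervals may be too narrow for counts of molecules. Intervals in parentheses are exact 95% intervals. A percentage of mouse reads means reads counted for the mouse entry, out of all reads counted for a mouse entry. Reads that start or end at another base of the hairpin were in many cases counted for another species' entry, so a second value "with end variants" adds the reads of such entries.

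A few miRNAs took most of the library. miR-148a-3p, a miRNA abundant in liver, held 3856275 reads, 57.9% of mouse reads (57.86 to 57.93). miR-1a-3p, a miRNA of heart and skeletal muscle, came next with 980271 reads or 14.7% (14.69 to 14.74). miR-122-5p followed with 236027 reads or 3.54% (3.53 to 3.56). Together these 3 miRNAs held 76.2% of mouse reads, and the 10 most abundant held 89.9%. The remaining members of the top 10 were let-7f-5p with 3.47%, miR-381-3p with 2.89%, miR-143-3p with 2.04%, let-7i-5p with 1.67%, let-7g-5p with 1.37%, miR-26a-5p with 1.18% and miR-192-5p with 1.08% of mouse reads. With end variants the same 3 miRNAs led, at 48.3%, 13.3% and 8.53%, but miR-126a-3p, miR-378a-3p and miR-30a-5p entered the top 10 at ranks 7, 8 and 9, and let-7g-5p, miR-26a-5p and miR-192-5p left it. Reads of miR-148a-3p outnumbered those of miR-1a-3p 3.93 to 1.

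**Figure D1:**
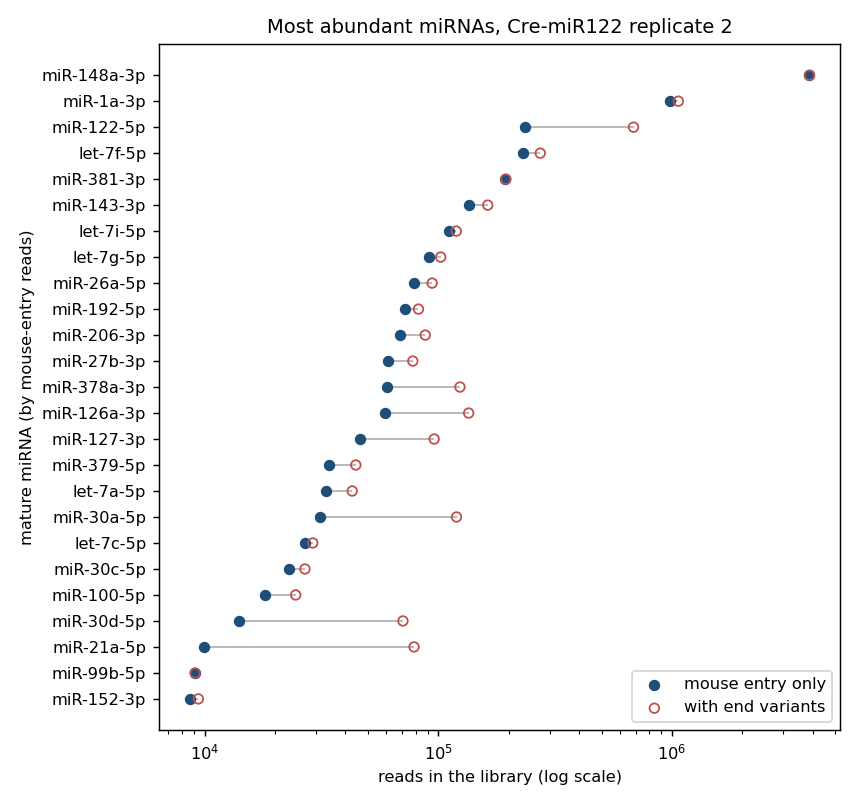
Reads of the 25 mature miRNAs with the most mouse-entry reads in Cre-miR122 replicate 2, on a log axis. Filled points are reads counted for the mouse entry and open points add end variants; miR-148a-3p stays near 3856275 reads, while miR-21a-5p moves from 9945 to 78762.

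On the mm10 (GRCm38) build, the gene of miR-148a-3p, Mir148a (ENSMUSG00000065505.1), lies on the minus strand of chromosome 6 from 51269812 to 51269910, in no other annotated gene. miR-1a-3p has copies at Mir1a-1 on chromosome 2, plus strand, from 180389048 to 180389124, outside other genes, and at Mir1a-2 on chromosome 18, minus strand, from 10785481 to 10785552. The Mir1a-2 copy lies in an intron of Mir133a-1hg and, on the opposite strand, of Mib1. The copies give the same mature sequence, so their reads cannot be separated. Mir381 (chromosome 12, plus strand, 109726822 to 109726896), Mir143 (chromosome 18, minus strand, 61649196 to 61649258) and Mir192 (chromosome 19, plus strand, 6264844 to 6264932) lie in no other annotated gene. The let-7f-5p sequence comes from Mirlet7f-1 in an exon of the noncoding gene 6720427I07Rik on chromosome 13 and from Mirlet7f-2 in an intron of Huwe1 on chromosome X. Mirlet7g lies in an intron of Wdr82 on chromosome 9, and Mirlet7i lies in an exon of the pseudogene D630033A02Rik on chromosome 10. miR-26a-5p comes from introns of Ctdspl on chromosome 9 and Ctdsp2 on chromosome 10.

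miR-122, after which the vector element is named, was present mainly as its 5p arm. Mir122 (ENSMUSG00000065402.1) lies on the plus strand of chromosome 18 from 65248861 to 65248926, in an exon of the long noncoding RNA gene AC157910.3, on mm10. The mature miR-122-5p, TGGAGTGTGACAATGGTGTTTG, spans 65248866 to 65248887. Its 22-nt mouse entry held 236027 reads, but 256101 reads were counted for an entry ending 1 nt earlier and 192825 for one ending 1 nt later. The mouse entry thus held 34.5% (34.3 to 34.6) of the 685102 reads on this arm. The 3p arm, miR-122-3p at 65248901 to 65248922, held 458 reads by its mouse entry and 777 with end variants. miR-122-5p had 515 reads per read of miR-122-3p (470 to 566), and 882 with end variants. Reads of miR-1a-3p outnumbered those of miR-122-5p 4.15 to 1 (4.13 to 4.17), which fell to 1.56 to 1 when end variants were counted. End variants match a hairpin exactly, so 84470 reads of miR-1a-3p with another last base are in neither ratio. Whether the miR-122 level differed from that of mice given Cre alone was not tested.

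**Figure D2:**
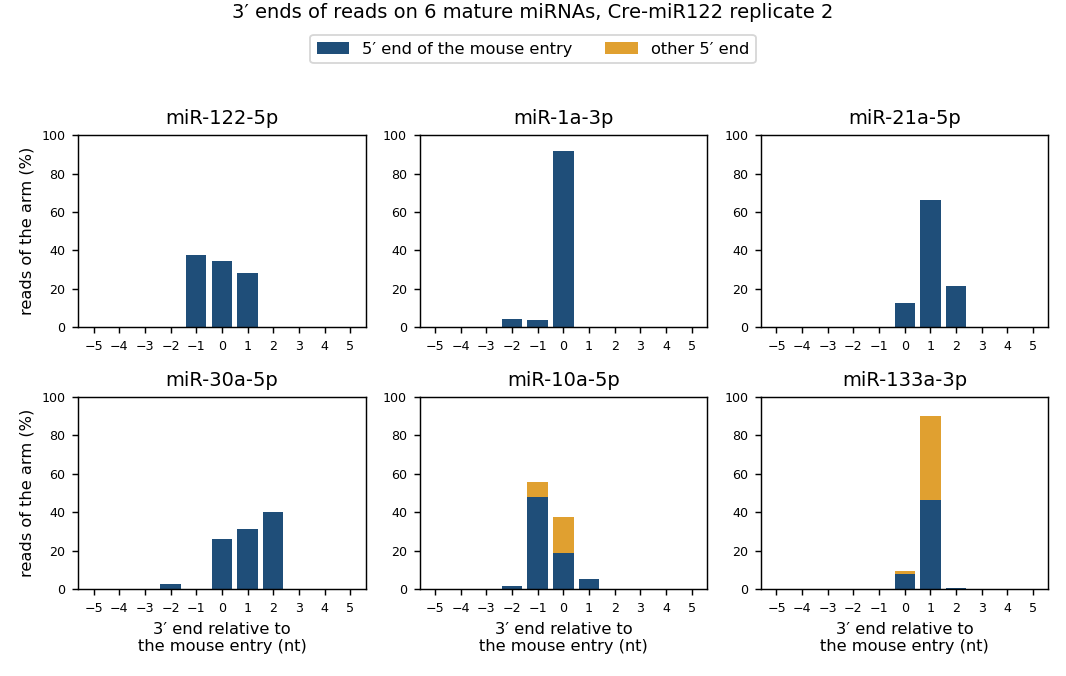
Share of the reads of 6 mature miRNAs by the position of their last base relative to the mouse entry, in nt, in Cre-miR122 replicate 2. Ends are those of the entries for which reads were counted. Bars are split by whether the first base is that of the mouse entry; miR-122-5p splits over 3 ends with 34.5% at the mouse end, and miR-21a-5p has 12.6% there.

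The 14 miRNA lists ranged from 0.00248% to 63.7% of mouse reads. Some lists share sequences, so their shares cannot be added. Another list also held 22 of 38 lipid and glucose metabolism sequences, 16 of 24 liver injury, hypoxia and p53 sequences and 7 of 7 miR-29 sequences. For the hepatocyte-enriched list this was 9 of 34. The striated muscle and heart, cholangiocyte and epithelial, let-7, miR-30 and Dlk1-Dio3 lists shared none. The hepatocyte-enriched list held 63.7% of mouse reads (63.66 to 63.74), with mouse-entry reads for 27 of its 34 sequences. miR-148a-3p alone made up 90.9% of it, followed by miR-122-5p. miR-192-5p had 72085 reads and miR-378a-3p had 60512, an order that reversed with end variants, at 82278 and 123839. Without miR-148a-3p in list and total, the list held 13.8%.

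The striated muscle and heart list held 15.8% of mouse reads (15.74 to 15.80), with mouse-entry reads for 8 of its 17 sequences. miR-1a-3p made up 93.3% of it. miR-206-3p, a miRNA of skeletal muscle, held 68854 reads or 1.03% of mouse reads. Mir206 lies on chromosome 1, plus strand, from 20679010 to 20679082, in an exon of the noncoding gene Gm28653. miR-133a-3p, which is co-transcribed with miR-1a, held 915 reads, or 11609 with end variants, against 1065891 of miR-1a-3p with end variants. miR-133b-3p, a list member named after its values were seen, held 20 reads, or 22 with end variants. The share of the list thus came mainly from miR-1a-3p and miR-206-3p, and its other members were low. miR-499-5p, from an intron of the myosin gene Myh7b, held 251 reads. Without miR-148a-3p in the total, the list held 37.4% of mouse reads, above the 13.8% of the hepatocyte-enriched list. Leaving out only the top member of each list, with the total unchanged, this list held 1.05% and the hepatocyte-enriched list 5.81%.

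Lists of nonparenchymal and blood cells held less. The stellate cell and fibroblast list held 2.36% (2.35 to 2.37), led by mouse entries of miR-143-3p with 135826 reads, miR-21a-5p with 9945, or 78762 with end variants, miR-199a-5p with 3574 and miR-335-3p with 2222. The endothelial list held 1.06% (1.05 to 1.07), of which miR-126a-3p, from the endothelial gene Egfl7, made up 84.1%. With end variants the endothelial share was 2.24%. The immune and Kupffer cell list held 0.0919%, or 0.162% with end variants. It was led by miR-146a-5p with 4090 reads, or 5906 with end variants, and miR-181a-5p with 1131, or 2864. The cholangiocyte and epithelial list held 0.0691%, or 0.165% with end variants, led by miR-200b-3p with 1425 reads, or 5791. The erythroid and blood list held 0.0504%, or 0.0861% with end variants. Its members miR-486a-5p and miR-486b-5p, which share 1 sequence, had 2549 reads, or 3066 with end variants, and miR-451a, a red blood cell miRNA, had 305, or 2635.

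Among lists of families and pathways, the let-7 family held 7.61% of mouse reads (7.59 to 7.63), led by let-7f-5p, let-7i-5p, let-7g-5p and let-7a-5p. The lipid and glucose metabolism list held 5.24% (5.23 to 5.26), in which miR-143-3p, miR-26a-5p, miR-27b-3p and miR-378a-3p were highest by mouse entries. The Dlk1-Dio3 cluster, an imprinted miRNA cluster on chromosome 12, held 4.57% (4.55 to 4.58). Of its 111 sequences 72 had mouse-entry reads and 10 more had reads as end variants only. miR-381-3p made up 63.2% of the list, ahead of miR-127-3p with 46251 reads, or 96047 with end variants, miR-379-5p with 34129 and miR-434-5p with 6167. The miR-30 family held 1.14%, or 2.90% with end variants, and was led by miR-30a-5p. By mouse entries miR-30c-5p came next with 22920 reads against 14040 of miR-30d-5p, and with end variants miR-30d-5p came next with 70602 against 26882. The liver injury, hypoxia and p53 list held 0.161%, of which miR-21a-5p made up 92.6%, and 0.997% with end variants. miR-34a-5p, whose gene is activated by p53, held 92 reads, or 157 with end variants. The miR-17-92 and related clusters held 0.112%, led by miR-25-3p with 5299 reads. The miR-29 family, which targets collagen mRNAs, held 0.00248%, or 0.0121% with end variants, and 158 of its 165 mouse-entry reads were miR-29a-3p, which had 904 with end variants.

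**Figure D3:**
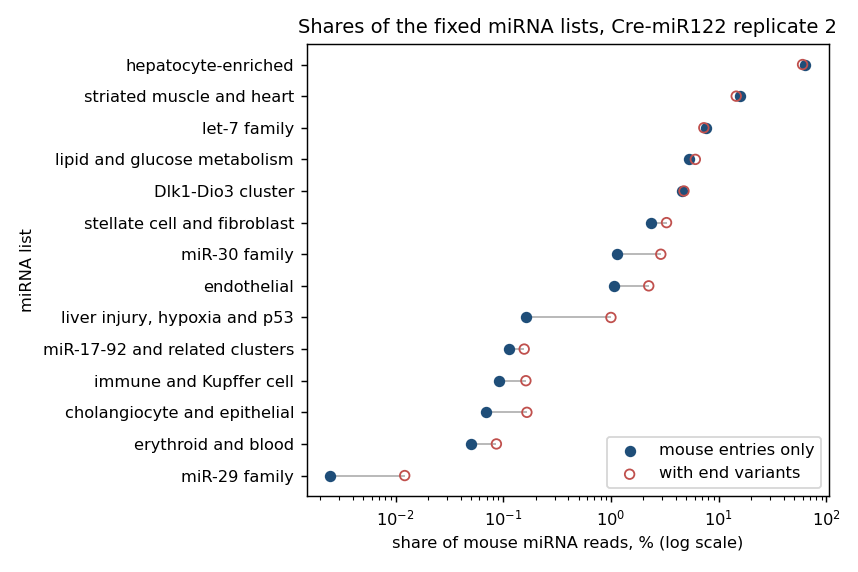
Share of mouse miRNA reads taken by each of the 14 miRNA lists in Cre-miR122 replicate 2, in percent on a log axis. Filled points count mouse entries only and open points add end variants. The hepatocyte-enriched list leads at 63.7%, followed by striated muscle and heart at 15.8%. Without miR-148a-3p, which makes up 90.9% of the hepatocyte-enriched list, the order by mouse entries reverses, at 13.8% against 37.4%. It does not reverse when the top member of each list is left out with the total unchanged, at 5.81% against 1.05%.

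The part of an arm that the mouse entry captured differed widely between miRNAs. Over the 28 arms with at least 10000 reads including end variants, the mouse entry held a median of 77.1% of the reads. It held under 50% in 12 arms and over 90% in 5. For miR-21a-5p it held 12.6% (12.4 to 12.9). An entry ending 1 nt later held 52055 reads and one ending 2 nt later held 16760. Counting these forms took the reads of miR-21a-5p from 9945 to 78762. For miR-30a-5p the mouse entry held 26.0% (25.8 to 26.3), for miR-30d-5p 19.9% (19.6 to 20.2) and for miR-148a-3p 99.4%. These values depend on which end forms other species' entries record, and end forms that no entry records are not seen.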

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

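All tests in this part were chosen after the values they bear on had been seen. Reads counted for entries of other species were data outside the main measurement, and both groups of them were far above the floor of 3 reads. In the first, 1386197 reads, 16.98% of all reads, were counted for 702 other-species sequences that lie inside mouse hairpins. In the second, 116536 reads, 1.43% of all reads, were counted for 210 other-species sequences found in no mouse hairpin.

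The first group goes with mouse entries that hold a small part of the reads of their arm. If only reads identical to a whole entry were counted, longer entries would often exceed the shorter entries nested in them, and this was so in 591 of 1129 nested pairs. Counting of every contained entry predicts 0 such pairs. Counting of whole reads, or another rule that gives each read to 1 distinct sequence, may therefore account for the low mouse-entry values of miR-21a-5p and miR-30d-5p, whose reads were 7.92-fold and 5.03-fold higher with end variants. These rules were not separated, and no biological explanation was tested.

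Most of the second group also lies near mouse hairpins. Of its reads, 112473, or 96.5%, differ from a mouse hairpin by at most 2 bases at the 3′ end, and 1021 reads by 1 substitution. Of the remaining 3042 reads, 2913 end in CCA, the ending of mature tRNAs.

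A single sequence made up 72.5% of the second group. It is miR-1a-3p with T22C, counted from 1 at the 5′ end, and was singled out after its values were seen. It had 84470 reads, 7.93% of the reads of both forms (7.88 to 7.98), while the 21-nt miR-1a-3p without that base had 41215. A rate of last-base errors common to all miRNAs was checked with miR-22-3p. It was the other sequence with at least 1000 mouse-entry reads in which T22C could be counted. There the change held 1.09% (0.713 to 1.59), from 26 reads. The miR-1a-3p pair was picked as the highest of 11, so a lower share in miR-22-3p was fixed in advance. The gap exceeds both intervals, but it rests on 1 comparison and does not decide the question. Among the 10 other pairs of a sequence and a last-base change, the highest were G22A in miR-126a-3p with 3.16% and in miR-206-3p with 2.89%. A base added after processing, a strain variant or an error particular to miR-1a-3p may still account for its T22C form. Neither the genome outside hairpins nor another library was searched.

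The library labelled liver held 15.8% striated muscle and heart miRNAs, from a list whose 17 sequences include 0 of any other list. A mislabelled muscle library with no liver RNA was checked with miR-192-5p, a liver and gut miRNA that the vector is not named after. It held 1.08% of mouse reads (1.07 to 1.09). The cut-off for this share was set after the share was seen, and no muscle or liver library was compared. The share therefore does not decide the question. miR-122-5p was not used, since the vector may encode it. Heart RNA alone was checked with miR-206-3p, which with end variants had 232 reads (210 to 257) per read of miR-208a-3p, miR-208b-3p and miR-499-5p together. The cut-offs for this ratio were also set after the values were seen. No heart or skeletal muscle library was compared, so the ratio does not decide this question either. With 1 library, heart or skeletal muscle taken with the liver and a mixture in any proportion may each contribute. So may reads of another library, levels usual for this liver preparation and an effect of the vector. None of these was settled here.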

How the results depend on the processing

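Counting end variants and leaving out miR-148a-3p were chosen after seeing the data, as was the count of sequences with at least 10 reads. With the total over all sequences of the table, miR-122-5p held 2.89% in place of 3.54%. With end variants counted, miR-122-5p held 8.53%, the hepatocyte-enriched list 60.0% and the striated muscle and heart list 14.5%, and the ratio of miR-1a-3p to miR-122-5p was 1.56 in place of 4.15. Without miR-148a-3p in list and total, the same 3 shares were 8.42%, 13.8% and 37.4%, and all these moves follow from the reads each alternative adds or removes. Without miR-122 features the lists held 62.4% and 16.3%. Restricting to at least 10 reads left 303 of 546 mouse sequences and moved neither the 81.6% of reads on mouse entries nor any of the 14 lists beyond its interval. Of the other 12 lists, 12 rose without miR-148a-3p by a common 2.37-fold, and 11 rose and 1 fell with end variants, from 0.955 to 6.18 times their main share. Comparisons that need several libraries were not run, namely other test tools, normalizations, filters, thresholds, set tests, summed copies and leaving out each replicate. No paired analysis was possible because 1 library was analysed and the groups share no replicate numbers. Depth limits miRNAs with few reads, such as miR-29b-3p with 2, or 8 with end variants, so that its value depends on the counting as well.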

Other observations

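The miRNAs in the next 2 paragraphs were singled out after their values were seen, unless a list names them. For 95 arms with at least 1000 reads including end variants, the first base was compared with that of the mouse entry, since a shifted first base moves the seed that pairs with targets. In 68 arms no read with another first base was recorded, and in 12 arms such reads exceeded 10%. In miR-133a-3p they made up 44.9% (44.0 to 45.8), with 5207 reads starting 1 nt later. In miR-10a-5p they made up 26.4% (25.9 to 26.9), with 8380 reads starting 1 nt later. In miR-126a-3p they made up 11.1% (10.97 to 11.3), with 12874 reads starting 1 nt earlier. The share was 54.0% in miR-101a-3p, 87.2% in miR-101b-3p, 91.8% in miR-136-3p and 49.5% in miR-140-3p. All 2023 reads of the miR-382-3p arm started at another base than the mouse entry. These shares cover the end forms that some species' entry records, and they take each read as identical to the entry it was counted for.

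Arm use was also counted with end variants. Of 68 hairpins with at least 1000 reads and arms of their own, the 5p arm had more reads in 41 and the 3p arm in 27. By mouse entries alone the split was 42 and 26, and the leading arm turned in 7 hairpins, Mir136, Mir200a, Mir27a, Mir30e, Mir329, Mir382 and Mir493. With end variants the leading arm held over 99% of the reads in 34 hairpins, among them Mir122 with 99.9% on its 5p arm and Mir126a, whose leading arm was 3p. In 5 hairpins the leading arm held under 75%. These were Mir329 with 55.4% on 5p, Mir382 with 54.5% on 3p, Mir423 with 56.2% on 3p, Mir30e with 64.2% on 5p and Mirlet7d with 73.6% on 5p. Of these, Mir329, Mir382 and Mir30e led on the opposite arm by mouse entries, with 525 reads on 3p against 204, 1542 on 5p against 0, and 1732 on 3p against 358. Arm totals depend on which end forms other species' entries record for each arm. In Mir329 end variants took 5p to 652 reads and left 3p at 525. All 2023 reads on 3p of Mir382 were counted for other species' entries.

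Some miRNAs of shared transcripts or of the same list were far apart in reads. miR-143-3p had 71.4 reads per read of miR-145a-5p (68.3 to 74.8), and 68.8 with end variants. Within the striated muscle and heart list, miR-206-3p had 75.3 reads per read of miR-133a-3p by mouse entries (70.5 to 80.4) and 7.58 with end variants. In the hepatocyte-enriched list miR-194-5p, from the cluster of miR-192, had 4017 reads, or 18596 with end variants, and miR-802-5p had 32, or 54. miR-145a-5p, miR-194-5p and miR-802-5p were named after their values were seen.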
